A study of Candida albicans with 10 samples.

How the data were processed

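RNA was measured in 10 Candida albicans SC5314 samples, 5 control and 5 treated with LL-37, by single-colour (Cy3) microarrays. Per the labels, the total RNA was amplified and labelled by in vitro transcription, and the design text speaks of independent experiments in 2 batches without saying which sample lies in which. The groups and replicate numbers were taken from the sample titles. Per the file headers, the authors' scanner software was Agilent Feature Extraction 10.5.1.1, which gave each spot's processed signal, an intensity on a linear scale after background subtraction and spatial detrending within the array. The deposited files also hold each spot's mean intensity and its local background intensity, and flags for outlier, saturated and well-above-background spots.

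The authors also deposited a value table in log2 units, with no stated scale or centring. Set against the scanner files, each of its columns equals the log2 processed signal, averaged over the 2 spots of a probe, minus 1 constant per array. The array with that constant difference was another replicate of the same group in all 10 columns, as the table's columns C1 to C5 match arrays 4, 5, 1, 2 and 3, and likewise for LL-37. The groups, and which samples pair with each other, are the same under either numbering; which numbering is right is not known. The column medians were 0.68 to 0.94. The direction of the table is that of the signal, and what its constant was is not given in the sources used here. It served as an alternative.

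From the scanner files, the log2 processed signals of the 2 spots per probe were averaged, leaving out control spots (536 per array) and 0 to 15 outlier spots per array, and the 75th percentile of the array's 12404 gene spots was subtracted. There was 1 probe of 60 bases per gene. The median processed signal was 4212 to 13085 per array, and the median absolute difference between the spots of a probe was 0.036 to 0.165 on the log2 scale. A gene was tested if its probe was well above background on at least 3 of 5 arrays of either group, which left out 101 genes and kept 6101. Genes are named as in the array files, where 2379 carry a symbol, of which 2343 are also in the reference table (assembly ASM18296v3, not used for coordinates), and 3823 have only an open reading frame identifier. Coordinates are those of the files, on Assembly 21, and cover the open reading frame; the exon or intron position of the probe was not determined.

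Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with group as the only term. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files and matplotlib 3.10.9 drew the plots. Gene lists fixed beforehand (32, each with at least 5 measured members) were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 32 lists; list members overlap in part. Designs, lists, thresholds and most alternatives were fixed before the data were examined. Lists were written from general knowledge of the species, not from these samples.

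The replicate numbers pair the samples. After subtraction of the group mean, the correlation across genes between the control and LL-37 samples of replicates 1 to 5 was 0.73, 0.56, 0.86, 0.88 and 0.90. All were above 0.1, a limit written after the pattern was seen, and every sample correlated best with its own number. The pairing comes from the replicate numbers in the titles and this check; the labels do not say that a number marks a shared culture or day. The replicate number accounted for 85.5% of the variance over all genes and the treatment for 6.58%. Samples of replicate 5 stood apart, with correlations of 0.929 to 0.959 with the other arrays of their group, against 0.975 to 0.992 among the others. No 2 arrays of a group were alike within the difference between spots; the smallest SD of their difference was 0.390. The labels do not say whether samples of a group came from separate cultures beyond calling the experiments independent, so p-values measure the spread between these samples. The eBayes step draws each gene's variance towards that of the other genes.

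The genes named in the text follow a rule fixed beforehand. They are the 12 largest rises and 12 largest falls past the threshold without overlap of the groups, up to 4 members per described list (those past the threshold, or the largest changes if fewer than 2 passed), and 11 fixed genes. As the unpaired fit called 0 genes, the first part was applied to the paired fit, with the same direction in all 5 pairs in place of non-overlap. This was chosen after the unpaired count was seen.

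Alternatives were normexp background correction (offset 50) of the mean and background intensity, quantile normalization, median centring, no filter on dim probes, a filter on all 10 arrays (5855 genes), the value table, blocks for replicate, slide and scan batch, trend and robust eBayes, array weights, an adjusted p of 0.01 and leaving out each sample. The paired fit under the same alternatives and without each pair was added after the data were seen. Leaving out genes with saturated spots and taking the brightest probe per gene were not run, since 0 spots were saturated and each gene had 1 probe. Scripts were tested on simulated data with the real means of the 6101 genes, with 200 genes, chosen at random, changed. Pair effects and errors were drawn at random with each gene's real spreads. For the comparison of LL-37 with control, the paired fit recovered 93 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 8 false calls among 200; the unpaired fit recovered 65 and 91, with 1 false call among 157. A list raised by 0.5 on the log2 scale was called by camera at both correlations and by fry, as the 1 of 32. The simulation drew genes independently and set no replicate apart, unlike the data, so its recovery may not hold for the real fits.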

Results

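Gene expression was measured in the fungal pathogen Candida albicans, strain SC5314, with and without LL-37. LL-37 is the human cathelicidin, a cationic antimicrobial peptide. Cultures grown for 3 h in a rich medium were washed and held for 30 min in RPMI medium, either alone (control, 5 samples) or with LL-37 at 5 ug/ml (5 samples). Each sample was labelled with Cy3 and hybridised to its own single-colour Agilent array of 6202 genes, with 2 spots per gene. Between 95.7% and 99.6% of gene spots were well above background, and 0 gene spots were saturated. The number of arrays limits the precision. The LL-37 array was brighter than the control array of the same replicate number in 5 of 5 pairs, by 0.21 to 0.49 on the log2 scale at the 75th percentile, and every value is given relative to that percentile of its array. A log2 change is LL-37 minus control.

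With LL-37, several nutrient transporter genes, carnitine acetyltransferase genes, glycerol genes and secreted protease genes fell, the largest by 13.9-fold (TNA1). The filamentation repressor gene NRG1, the yeast-form genes YWP1 and RHD1 and 3 ribosome assembly genes rose by less than 2-fold. These calls come from the fit in which the replicate number is a block, because samples sharing a number deviated together. In that paired fit 72 of 6101 genes passed an adjusted p of 0.05, of which 27 rose and 45 fell, and each of the 72 moved the same way in all 5 pairs. A change of at least 2-fold was seen for 20 of them, 1 higher and 19 lower. In the limma fit without the block, which was the design fixed beforehand, 0 genes passed, the smallest adjusted p was 0.487 and 94 genes had an unadjusted p under 0.05 (29 higher, 65 lower). With array weights that unpaired fit called 5 genes. Of the 6101 genes, 21.3% moved the same way in all 5 pairs, against 6.25% by chance, while the 5 values of one group lay wholly apart from those of the other for 0.393% of genes. Chance gives 0.794% for independent samples, a value that does not take the pairing into account. The paired count was lower with fewer pairs, at 47, 16, 19, 12 and 24 without replicates 1, 2, 3, 4 and 5 in turn. Rises numbered 14, 1, 4, 1 and 2 in these fits and falls 33, 15, 15, 11 and 22, and at an adjusted p of 0.01 there were 1 rise and 11 falls. Of the 35 named genes called in the paired fit, 9 passed in all 5 fits without 1 pair: TNA1, HGT12, HGT10, RHR2, PHO113, orf19.2468, orf19.4189, orf19.5975 and, as the 1 rise, orf19.3988. Each of the others passed in at most 3 of these fits: SAP4 in 3, GAP2, PHO112, TPO3, UTP21 and orf19.3954.1 in 2, and KRE6, PGA34, SAP6, TSR1, YTM1 and orf19.2330 in 0. The rest, among them CTN1, CTN3, HGT17, SAP5, HYR1, NRG1, YWP1, RHD1 and RTA3, passed in 1. The split also moved with the scaling. Under quantile normalization 26 genes rose and 27 fell, and with the authors' deposited values 56 rose and 43 fell. The verbs rose and fell are used only of genes that passed the paired test over all genes. Higher and lower give the direction of a change and do not by themselves mean that a test was passed. Where genes passed adjusted over their list alone, this is said.

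**Figure D1:**
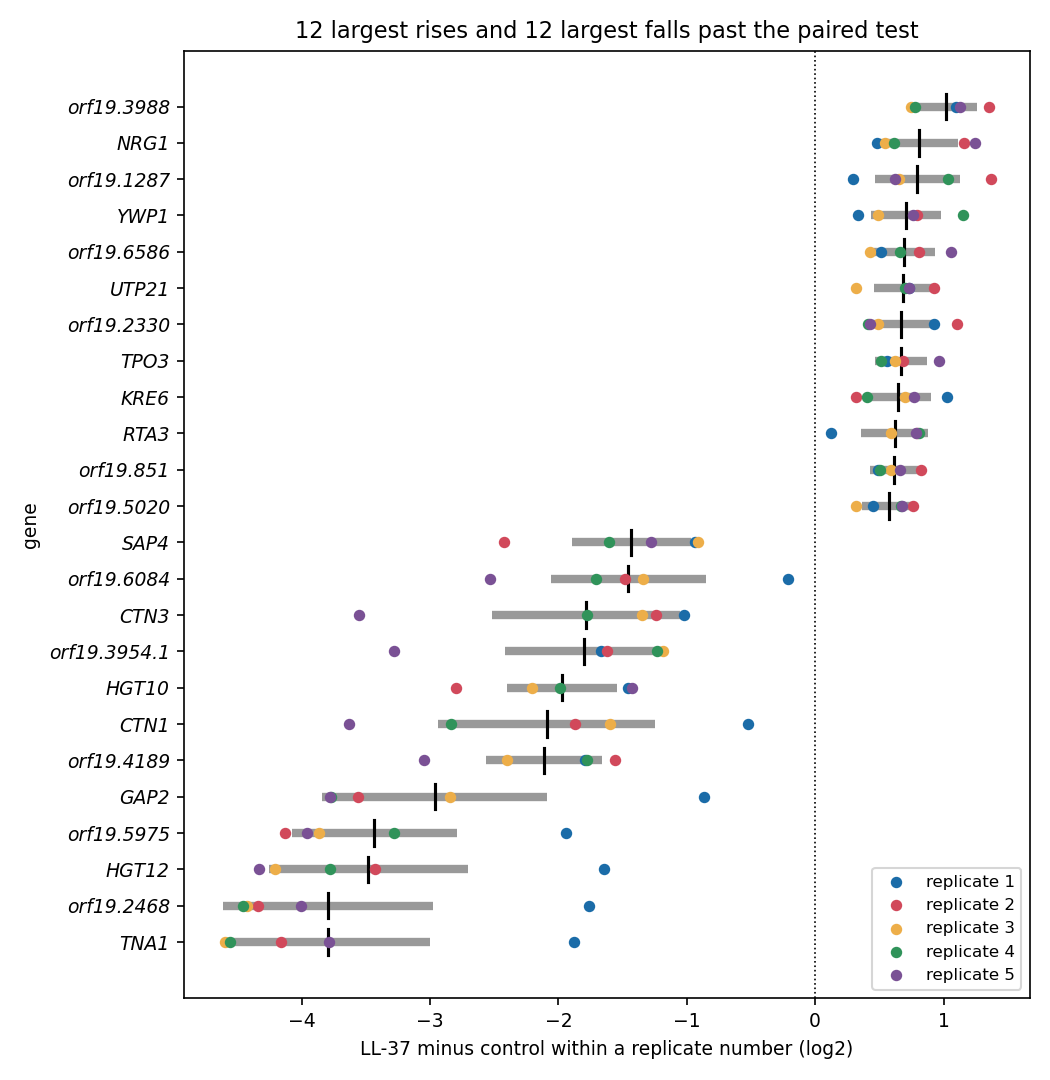
The 12 largest rises and 12 largest falls among genes past the paired test, with the log2 change (LL-37 minus control) on the horizontal axis. Coloured points are the 5 pairs, black ticks their mean and grey bars the 95% interval of the paired fit; the falls of TNA1, HGT12 and GAP2 were smallest in replicate 1, and orf19.3988 showed the largest rise at 1.02.

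Of the 5 largest falls, 3 were in genes for uptake of nutrients. TNA1, a putative nicotinic acid transporter (chromosome 5, open reading frame at 679558 to 681090 of Assembly 21), fell from -0.97 ± 2.08 in control to -4.77 ± 1.74 with LL-37 (SD, n = 5 each). This is a 13.9-fold fall, with a 95% interval of 7.99 to 24.2 and an adjusted p of 0.00356. Both rest on the eBayes variance, which draws on other genes. The SD over the 5 pairs of TNA1 was 1.12, and its smallest fall was -1.88 on the log2 scale, in replicate 1. HGT12, a hexose transporter of the major facilitator superfamily (chromosome 7, 41587 to 43167), fell 11.2-fold, from -0.05 ± 2.04 to -3.53 ± 1.44 (SD, n = 5; adjusted p = 0.00369). GAP2, an amino acid permease (chromosome 3, 1246890 to 1248656), fell 7.81-fold, with a log2 change of -2.96 ± 1.23 (SD over 5 pairs; adjusted p = 0.0181). The glycerol permease HGT10 (chromosome 6, 817528 to 819168) fell 3.93-fold with an adjusted p of 0.00356, and its control and LL-37 values did not overlap. The glucose transporter family member HGT17 fell (adjusted p = 0.0269) at a low signal, being well above background on 5 control arrays and 3 LL-37 arrays. The size of its fall is therefore uncertain, with a log2 change of -1.19, and -0.57 under normexp. In the list of hexose transport and sensing genes, 2 of 19 measured members fell over all genes tested and 2 passed adjusted over the list alone; the list as a whole had a median change of -0.10 and did not pass (adjusted p = 0.125, paired camera). It passed with the slide as a fixed block (median -0.42, adjusted p = 3.74e-06) or a random block (-0.29, 9.93e-05), and not with the scan batch as a block (-0.17, 0.0706). Its pair medians were 0.29, -0.11, 0.05, -0.20 and -0.75 for replicates 1 to 5. Here and below, the fixed slide block rests on replicates 4 and 5 alone, the only pairs on a shared slide. The random slide block also gives these pairs more weight than the others. In the paired fit the list passed without replicate 1 (median -0.23, adjusted p = 0.00106) or 3 (-0.17, 0.0432). Its median was 0.0060 without replicate 5. Among 35 nitrogen and peptide uptake genes, GAP2 alone fell over all genes, while 2 higher and 3 lower members passed adjusted over the list alone (list adjusted p = 0.152). This list, too, passed with the slide as a fixed block (median -0.27, adjusted p = 5.01e-06) or a random block (-0.19, 0.00036), and not with the scan batch as a block (-0.11, 0.0905). Its pair medians were 0.32, -0.0010, 0.0072, -0.20 and -0.36 for replicates 1 to 5. In the paired fit it passed without replicate 1 (median -0.13, adjusted p = 0.00265) or 3 (-0.14, 0.046). AGP2 and OPT4 of that list had changes of -0.78 (adjusted p = 0.0528) and -0.75 (adjusted p = 0.0675). Without replicate 5, which stood apart from the other replicate numbers in both groups, the paired count was 24.

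The carnitine acetyltransferase genes CTN1 (chromosome 1, 357096 to 359483) and CTN3 (chromosome 3, 832506 to 835184) fell 4.26-fold and 3.45-fold (adjusted p = 0.0427 and 0.0442). Of the 28 measured genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation, 25 were lower with LL-37, 2 fell over all genes tested and 6, all lower, passed adjusted over the list alone. The list's median change was -0.28, with pair medians of -0.15, -0.06, -0.17, -0.20 and -0.78 for replicates 1 to 5. It passed camera with its preset correlation in both fits (adjusted p = 3.75e-05 unpaired and 1.18e-05 paired). It did not pass with an estimated correlation (adjusted p = 0.824 and 0.834), nor in the unpaired fit without both samples of replicate 5 (median -0.11; adjusted p = 0.0796). The 22 glycolysis and fermentation genes had a median change of 0.00 with 11 members higher, whose sign was opposite to that of the paired test (adjusted p = 0.624) and turned negative under median centring, normexp and the slide and scan batch blocks. Without replicate 2 this list passed in the paired fit, with a median of -0.092 (adjusted p = 0.0363). The 46 genes of the tricarboxylic acid cycle and respiration had a median of 0.04 (adjusted p = 0.488, paired). Neither list had a member past the test.

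The glycerol phosphatase gene RHR2, which makes the osmolyte glycerol (chromosome 3, 45115 to 45879), fell 2.52-fold, with a log2 change of -1.33 ± 0.28 (SD over 5 pairs) and an adjusted p of 0.00356. RHR2 and HGT10 were the 2 of 24 osmolyte and trehalose genes that fell; the same number passed adjusted over the list alone, and 1 did in the unpaired fit. That list had a median of -0.06 and 10 members higher. It passed the preset test in the unpaired fit (adjusted p = 0.0226) but not in the paired one (adjusted p = 0.0636), nor with an estimated correlation (adjusted p = 0.824 unpaired), the scan batch as a block (0.0805) or replicate 5 left out (0.375). With the slide as a fixed or a random block it passed (adjusted p = 0.000178 and 9.93e-05). The acid phosphatase genes PHO113 (chromosome R, 478042 to 479430) and PHO112 (chromosome R, 533720 to 535105) fell 1.88-fold and 1.67-fold (adjusted p = 0.00389 and 0.0224). Of 15 phosphate genes, these 2 fell and 11 were lower, and 1 higher and 2 lower members passed adjusted over the list alone. The phosphate list, with a median of -0.14, missed the threshold in both fits (adjusted p = 0.0755 unpaired and 0.051 paired). It passed with the slide as a fixed block (adjusted p = 0.0198) or a random block (0.0247), and not with the scan batch as a block (0.567). It also passed with the filter on all 10 arrays (0.0497 unpaired, 0.0327 paired) and, in the paired fit, with the authors' deposited values (0.0438).

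The secreted aspartyl proteinase genes SAP4 (chromosome 6, 745130 to 746383), SAP6 (chromosome 6, 558311 to 559567) and SAP5 (chromosome 6, 635336 to 636592) fell 2.70-fold, 2.48-fold and 2.24-fold (adjusted p = 0.0224, 0.046 and 0.0427). The probes of SAP4 and SAP6 share a run of 30 bases and match at 52 of 60 bases when aligned without gaps, so these genes cannot be separated with certainty. The SAP5 probe shares at most 7 bases in a row with either probe. Probes were compared only with each other and not with the other transcripts, so whether SAP5 is measured separately was not tested. HYR1, a hypha-induced cell wall protein (chromosome 1, 2944794 to 2947553), fell 1.81-fold (adjusted p = 0.0393). These 4 are all the hyphal growth genes, of 30 measured, that fell over all genes tested, with 0 rising; 2 higher and 6 lower members passed adjusted over the list alone. The median change of the list was -0.12, and it was below 0 in 5 of 5 pairs. The list did not pass in the unpaired fit (adjusted p = 0.0927). It passed in the paired fit (0.0405) and with a block for the slide (0.0174 fixed, 0.0403 random) or the scan batch (0.00485). The paired call was lost with an estimated correlation (adjusted p = 0.834), normexp (0.142) or array weights (0.0568), and without replicate 4 (0.0942) or 5 (0.118). In the list of yeast-form genes and repressors, NRG1, which encodes a repressor of hyphal genes (chromosome 7, 918848 to 919780), rose 1.75-fold (95% interval 1.42 to 2.16; adjusted p = 0.0375). YWP1, a yeast-form wall protein (chromosome 2, 1747033 to 1748634), rose 1.63-fold (adjusted p = 0.0412), and RHD1, a putative beta-mannosyltransferase (chromosome 1, 1048370 to 1050334), rose 1.49-fold (adjusted p = 0.0224). Over all genes these 3 of 13 rose, and 4, all higher, passed adjusted over the list alone; 11 were higher. The median was 0.31, above 0 in 5 of 5 pairs, with an adjusted p of 0.00336 unpaired and 0.00198 paired, and of 0.824 and 0.834 with an estimated correlation. With the slide as a fixed block the list did not pass (median 0.17; adjusted p = 0.0643), nor did it in the paired fit without replicate 2 (0.0526). The white and opaque list, cells of a mating-related switch, had 8 of 9 members higher and 0 past the test, led by WH11 at 0.42 and WOR2 at 0.30 (adjusted p = 0.136 and 0.262). This list mixes markers of both forms, so its direction favours neither, and it shares WH11 with the yeast-form list. It passed in the paired fit (adjusted p = 0.0489) and with the slide as a fixed block (0.0124), not in the unpaired fit (0.0998) or with the slide as a random block (0.0772) or the scan batch (0.0805). The paired call was lost with an estimated correlation (adjusted p = 0.834), normexp (0.217), array weights (0.0668) or the filter on all 10 arrays (0.0636), and without replicate 2 (0.0816), 4 (0.0685) or 5 (0.132).

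All 71 measured ribosome biogenesis genes had a higher mean with LL-37, with a median log2 change of 0.28 and pair medians of 0.13, 0.59, 0.13, 0.36 and 0.35 for replicates 1 to 5. UTP21, of the small-subunit processome (chromosome 2, 481408 to 484236), rose 1.61-fold, YTM1, of large-subunit assembly (chromosome 1, 2093301 to 2094701), rose 1.45-fold, and TSR1, of small-subunit assembly (chromosome R, 1832468 to 1834996), rose 1.44-fold. Their adjusted p values were 0.0231, 0.0453 and 0.0269. These were the 3 that rose over all genes tested, while 41 passed adjusted over the list alone. The list passed the preset test (adjusted p = 1.74e-06 unpaired and 1.72e-21 paired) and not the one with an estimated correlation (adjusted p = 0.84 and 0.834). Its median was 0.28 without both samples of replicate 5. With single samples left out, which unbalances the groups, the unpaired call was lost without control replicate 5 (median -0.018; adjusted p = 0.872) and without LL-37 replicate 1 (0.076; 0.0742), and the median was 0.61 without LL-37 replicate 5. The 8 genes of RNA polymerases I and III had a median of 0.20 with 7 higher, 0 past the test over all genes and 2, both higher, past it adjusted over the list alone. RPA12 and RPA135 had changes of 0.29 and 0.28 (adjusted p = 0.188 and 0.116). This list passed in the paired fit (adjusted p = 0.0096), with the slide as a random block (0.0403) and with the scan batch as a block (0.0219). It did not pass in the unpaired fit (adjusted p = 0.0755), with the slide as a fixed block (0.0685) or, paired, with an estimated correlation (0.834).

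**Figure D2:**
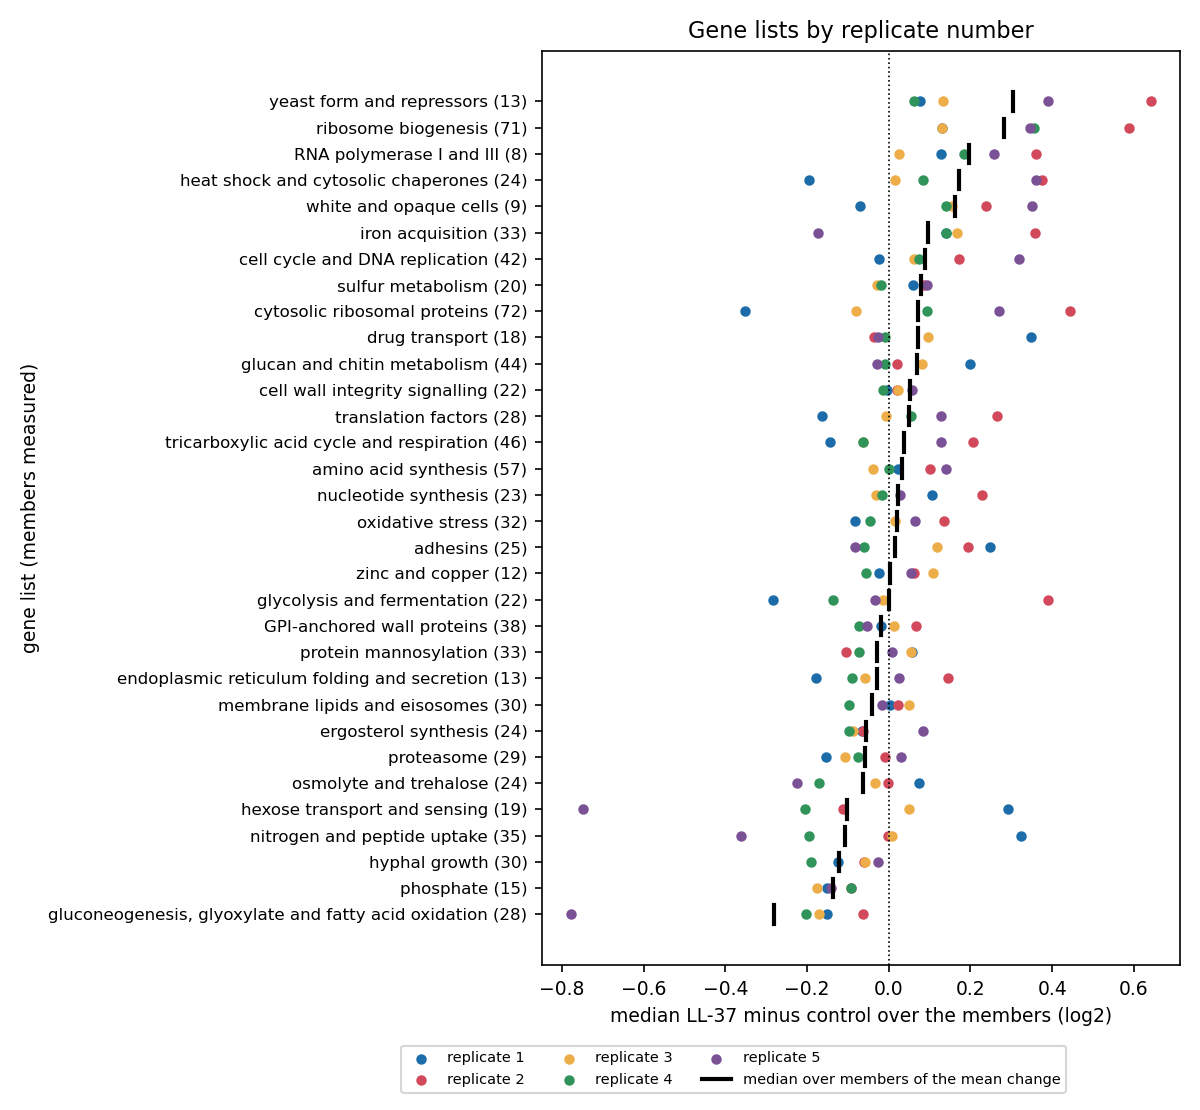
Median log2 change (LL-37 minus control) over the measured members of each of the 32 gene lists, per replicate number (coloured points) and for the mean over pairs (black ticks). Ribosome biogenesis and the yeast-form list lie above 0 in all 5 pairs and gluconeogenesis below 0 in all 5, whereas cytosolic ribosomal proteins range from -0.35 to 0.44.

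The remaining lists past the preset test held no gene past the paired test over all genes. The 72 cytosolic ribosomal protein genes had a median of 0.07, with 57 members higher but pair medians of -0.35, 0.44, -0.08, 0.09 and 0.27, so that the direction differed between pairs. RPS27A and RPS30 had changes of -0.40 and 0.34 (adjusted p = 0.131 and 0.126). The adjusted p of the list was 0.0112 unpaired and 0.0281 paired, and 0.946 and 0.834 with an estimated correlation; without replicate 2 the paired median was -0.03 (adjusted p = 0.924), and without replicate 4 the adjusted p was 0.0705. The call was lost with the scan batch as a block (median 0.03; adjusted p = 0.437), array weights (0.117 unpaired, 0.289 paired) and replicate 5 left out (0.27 unpaired, 0.171 paired). Of 24 genes for heat shock proteins and cytosolic chaperones, 21 were higher, with a median of 0.17 (adjusted p = 0.00523 unpaired, 0.0112 paired, 0.824 and 0.834 with an estimated correlation). Without replicate 5 it did not pass (adjusted p = 0.0796 unpaired, 0.0542 paired), nor with array weights in the unpaired fit (0.126) or without replicate 2 in the paired one (0.184). HSP12 and ASR2 of that list had changes of 0.31 and 0.24 (adjusted p = 0.406 and 0.488). Of 42 cell cycle and DNA replication genes, 31 were higher, with a median of 0.09 (adjusted p = 0.00339 unpaired, 0.00572 paired, 0.824 and 0.834 with an estimated correlation). The unpaired call was lost with the scan batch as a block (adjusted p = 0.0803) and without replicate 5 (0.0796). PCL7 and PCL1 showed the largest changes there, at -0.69 and 0.52 (adjusted p = 0.374 and 0.202), and 1 gene of the list, a higher one, passed adjusted over the list alone. In all, 7 of 32 lists passed in the unpaired fit and 9 in the paired fit, 6 of them in both, and 0 passed in either fit with an estimated correlation or with fry. Of the 10 unpaired fits without 1 sample, which unbalance the groups, the yeast-form list passed in 10, gluconeogenesis and cell cycle in 9, ribosome biogenesis in 8, heat shock in 7, osmolytes in 6 and cytosolic ribosomal proteins in 5. The order differed in the 5 paired fits without 1 pair. There ribosome biogenesis, gluconeogenesis, cell cycle and RNA polymerases I and III passed in 5 and the yeast-form list in 4. Heat shock and hyphal growth passed in 3, and cytosolic ribosomal proteins and the white and opaque list in 2.

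At the cell wall and membrane, KRE6, of beta-1,6-glucan synthesis (chromosome 3, 1306203 to 1308425), rose 1.56-fold, and its control and LL-37 values did not overlap (adjusted p = 0.0427). It was the 1 of 44 glucan and chitin genes that rose over all genes, and the 1 that passed adjusted over the list alone. The median of that list was 0.07 (adjusted p = 0.196, paired), turned negative with the slide as a block, and passed with array weights (0.0286 unpaired, 0.0472 paired). TPO3, an exporter with a possible role in polyamine transport (chromosome 1, 1914936 to 1916693), rose 1.59-fold (adjusted p = 0.0216); it was the 1 of 18 drug transport genes past the test, while 4 higher genes and 1 lower gene passed adjusted over the list alone (list adjusted p = 0.192). RTA3, a putative membrane protein related to lipid flippases (chromosome 2, 1314829 to 1316223), rose 1.54-fold (adjusted p = 0.0454) and was the 1 of 30 membrane lipid and eisosome genes past the test over all genes, with 2 higher and 3 lower genes past it adjusted over the list alone (median -0.04; list adjusted p = 0.591). Of 38 GPI-anchored wall proteins, YWP1 rose and PGA34 fell 1.62-fold (adjusted p = 0.0442); 3 higher and 2 lower genes passed adjusted over the list alone (median -0.02, positive with the authors' deposited values; list adjusted p = 0.622, and 0.0317 with the slide as a fixed block, where the median was -0.16). That list did not pass with the slide as a random block (adjusted p = 0.278) or the scan batch as a block (0.437). The 25 adhesins had a median of 0.02, which turned negative under normexp and the slide blocks, and HYR1 was the 1 member past the test, with 2 higher genes and 1 lower gene past it adjusted over the list alone (list adjusted p = 0.475).

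Other large changes were in genes with little or no description in the array annotation. The open reading frame orf19.2468 (chromosome 1, 1213982 to 1214902) fell 13.9-fold, and orf19.5975, annotated as a putative zinc finger transcription factor (chromosome 3, 1087657 to 1088517), fell 10.8-fold, both with an adjusted p of 0.00356. The genes orf19.4189, orf19.3954.1 and orf19.6084 fell 4.33-fold, 3.48-fold and 2.74-fold (adjusted p = 0.00356, 0.0258 and 0.0453). The largest rise was that of orf19.3988 (chromosome 5, 1095702 to 1097429), at 2.03-fold with a 95% interval of 1.72 to 2.40 (adjusted p = 0.00464). Rises of 1.49-fold to 1.74-fold were found for orf19.1287, orf19.6586, orf19.2330, orf19.851 and orf19.5020 (adjusted p from 0.0216 to 0.0453); the array annotation calls orf19.1287 a possibly spurious reading frame.

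A set of wall, adhesion and signalling genes was chosen in advance whatever its result, and none of those measured passed the test over all genes in either fit. XOG1, an exo-glucanase of the cell wall, had a log2 change of 0.18 ± 0.09 (SD over 5 pairs; adjusted p = 0.245, paired), and was higher in 5 of 5 pairs. The adhesin genes ALS1 and ALS3 had changes of -0.04 ± 0.32 and -0.32 ± 0.60, HWP1 one of -0.27 ± 0.50 and the wall protein gene RHD3 one of -0.06 ± 0.16 (SD over 5 pairs; adjusted p = 0.883, 0.4, 0.412 and 0.745). Among kinases of stress and wall signalling, CEK1 was lower in 5 of 5 pairs, at -0.40 ± 0.18 (adjusted p = 0.072 over all genes and 0.04 over its list alone). MKC1 was higher in 5 of 5 pairs at 0.15 ± 0.06 (adjusted p = 0.283), and HOG1 was at -0.06 ± 0.17 (adjusted p = 0.753). The oxidative stress regulator gene CAP1 was at 0.17 ± 0.26 (adjusted p = 0.419) and the actin gene ACT1 at -0.04 ± 0.23 (adjusted p = 0.852). No probe carries the symbol SFP1.

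The arrays lay on 7 slides and were scanned in 5 batches. With the slide or the scan batch as a fixed block, or the slide as a random block, 0 genes passed. The unadjusted p was under 0.05 for 150, 657 and 360 genes. These fits have no term for the replicate number, which accounted for 85.5% of the variance. The 0 calls therefore cannot tell whether the paired calls depend on slide or scan. Both groups were present on slides 1 and 7 and in scan batches 1, 2, 3 and 5. The change of TNA1 was -4.56 within slide 1 and -3.78 within slide 7, which were also scan batches 1 and 5, -1.88 within scan batch 2 and -3.38 within scan batch 3. The corresponding values of HGT12 were -3.78, -4.34, -1.65 and -2.89, and those of NRG1 were 0.62, 1.24, 0.48 and 1.19. The ribosome biogenesis median was 0.36, 0.35, 0.13 and 0.31 in the same 4 batches. The gluconeogenesis median was -0.20, -0.78 and -0.15 in the first 3 of these and 0.10 in scan batch 3, which held control replicates 2 and 3 and LL-37 replicate 2. With the slide as a fixed block the medians of these lists were 0.36 and -0.51, and with the scan batch they were 0.27 and -0.27. The within-batch values are no separate check of the calls. Slide 1, slide 7 and scan batch 2 hold pairs 4, 5 and 1, whose values gave the calls. Scan batch 3 holds pair 2. Of the 72 genes called in the paired fit, all of which moved the same way in all 5 pairs, 69 had the same direction within scan batch 3. PHO112, at 0.41, was among the exceptions. The other slides and scan batch 4 held samples of 1 group only and give no value.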

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

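The tests of the slide, the scan batch, the brightness of the arrays, signal level, GC content and shared variation between members were chosen after the patterns were seen, whereas the counts of splits were planned before their results. A sample was singled out where its gap to the nearest of the other 4 exceeded 0.71 of the range of 5 values. This happened in 26 of 211 groups of 5, and chance alone gives about 1 in 20.

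Replicate 5 was the sample apart in many of these. In control it was lowest for HWP1 (gap 0.759 of the range), ALS3 (0.721) and NAG3 (0.759) and highest for RPS27A (0.725) and HGT17 (0.742). Among LL-37 samples it was lowest for orf19.1287 (0.785), ALS3 (0.73) and NAG3 (0.831) and highest for CEK1 (0.88), RPS27A (0.869), CHT4 (0.799) and OPT4 (0.733). The pair difference of replicate 5 was the lowest of the 5 for orf19.3954.1 (0.771), FAD3 (0.74) and the median of the gluconeogenesis list (0.806). LL-37 replicate 3 was highest for SAP4 (0.936) and SAP6 (0.866), and replicate 3 was highest for PGA34 in control (0.855) and with LL-37 (0.713).

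Single genes stood out in single samples. PCL7 lay at -4.24 in LL-37 replicate 3 and between -1.45 and -0.90 in the other LL-37 samples (gap 0.835 of the range), so that its pair difference was -2.98 there (gap 0.867). CHT4 was 2.66 higher with LL-37 in replicate 1 and between -0.59 and 0.01 in the other pairs (gap 0.817). The fall of orf19.2468 was smallest in replicate 1, at -1.76 (gap 0.832). The 75th percentile of the signal was highest in replicate 1 of both groups (0.762 and 0.739), and LL-37 replicate 4 had the largest difference between spots, 0.165 (0.842).

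The first pattern weighed is that samples with the same number deviated together. A shared slide as the only cause is argued against by the pairs on different slides, whose lowest correlation was 0.558. A contribution of the slide is not excluded. Pairs 4 and 5, each on a shared slide, had the highest correlations (0.876 and 0.905), against 0.727, 0.558 and 0.856 for pairs 1 to 3. A shared scan as the only cause is argued against by pair 3, whose samples were scanned in different batches and correlated at 0.856. A shared culture, day or RNA preparation stays open, as the labels name none; no biological explanation was tested.

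The second pattern is the fall of 45 genes in the paired fit. The LL-37 arrays were brighter, which could lower dim genes once arrays are scaled. Before scaling the median change of the 45 was -0.54, with an SD of 0.27 over the 5 pair medians, and all 45 had a lower mean. Scaling subtracts 1 constant per array, so this shows only that each of the 45 fell by more than the mean brightness difference. These genes were picked for their falls, which favours that outcome, so a contribution of brightness is not excluded. Other genes of the same signal level had a median change of -0.00090 on average, so a trend with signal level is argued against. Treatment with LL-37 stays open, as a hypothesis found and tested on the same data. The 5 pairs allow 16 splits that part every pair, too few for a share under 0.05; the real split called 72 genes and 20 with at least a 2-fold change, the highest of the others 0 in both cases, and 1 split of 16, the real one, was as large.

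The third pattern is that all 71 ribosome biogenesis genes were higher. A trend with signal level or probe GC content is argued against, since the median was 0.29 after a fit on both. Members may vary together between cultures, so that their number adds little. In the unpaired fit, which keeps the variation between cultures, the estimated correlation between members was 0.878, as this explanation needs. The list was not called with it (adjusted p = 0.84). As 0 of the 32 lists were called in that way (smallest adjusted p 0.824), the missing call does not bear on this explanation. In the paired fit that correlation was 0.384, which neither excludes nor establishes it. The treatment stays open beside it.

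The splits bear on the number of lists called. Of the 100 splits drawn of the 10 samples, 85 gave at least the 7 lists of the real split, with a highest other of 17, so chance cannot be excluded; of the 16 paired splits 7 gave at least the 9 of the real one, the highest other being 15. For the unpaired count of genes the splits say nothing about chance, since the real count is 0 and all 100 reach it by construction. The highest of the others, which parted 1 pair, called 200 genes, which points to a structure of the samples. The 8 other drawn splits that part all 5 pairs, as the real one does, called 0 genes each, had 1 to 20 genes at an unadjusted p under 0.05 against 94, and called 5 to 13 lists.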

How the results depend on the processing

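The paired fits under other settings, and the fits without both samples of replicate 5, were chosen after the data were seen. The unpaired count of 0 genes, overall and at 2-fold, was 0 under the other scalings, filters and batch blocks, without any single sample and without replicate 5. It became 5 and 5 with array weights, and 72 and 20 with the replicate block. The 7 lists of the unpaired fit were 12 with the slide as a fixed or a random block, 3 without replicate 5, 0 with an estimated correlation, 0 with fry and 4 to 13 without single samples (4 without control replicate 5, 13 without control replicate 1). Counts of 11 or 12 came without control replicate 3 or LL-37 replicate 1, 4 or 5. Leaving out saturated spots and taking the brightest probe were not run, as 0 spots were saturated and each gene had 1 probe.

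In the paired fit, the 72 genes were 186 with normexp, 134 with trend and robust eBayes, 332 with array weights, 113 with the filter on all 10 arrays (fewer genes tested), 39 with no filter and 12 at an adjusted p of 0.01; quantile normalization, median centring and the value table gave 53, 61 and 99. Of the 72, 67, 64, 72, 65, 39, 12, 47, 59 and 69 were among these, in that order. Without single replicates the count was 12 to 47 with fewer samples, lowest without replicate 4 and highest without replicate 1, and 2-fold changes were 9 to 19 (9, 10 and 13 without replicates 2, 4 and 5) against 20. The 2-fold count at an adjusted p of 0.01 was 9. The 9 lists were 0 with an estimated correlation, 0 with fry and 6 to 14 without single replicates (14 without replicate 1, 6 without replicate 4 or 5). Apart from what is said of samples left out and of adjusted p, the cause was not tested.

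List medians turned in sign when single samples were left out, which unbalances the groups with respect to replicate number in the unpaired fit; without both samples of replicate 5 the ribosome biogenesis median was 0.28. The median change of the ribosome biogenesis list was -0.018 without control replicate 5 and 0.61 without LL-37 replicate 5. That of the amino acid synthesis list was -0.29 without LL-37 replicate 5 and 0.31 without control replicate 5. That of the cytosolic ribosomal proteins list was -0.017 without control replicate 4 and 0.20 without control replicate 1, and with the replicate block it was -0.029 without replicate 2 and 0.20 without replicate 1. That of the glycolysis and fermentation list, with the replicate block, was -0.092 without replicate 2 and 0.093 without replicate 1. No named gene past the threshold turned. Signal over background limits the lowest genes, such as HGT17 with 3 LL-37 arrays well above it.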

Other observations

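The test of transporters below was chosen after the names of the fallen genes had been seen, and the test of the main difference between replicate numbers was written before its result. Other lists did not pass in either fit. In the paired test the adjusted p was 0.0782 for iron acquisition (25 of 33 higher, median 0.10; 1 higher and 1 lower gene passed adjusted over the list alone; 3.03e-05 without replicate 5 and 0.0057 with array weights, and a negative median with the slide as a fixed block), 0.51 for sulfur metabolism (median 0.08; 1 higher and 2 lower genes passed adjusted over the list alone), 0.21 for ergosterol synthesis (-0.06; 0.0495 with the scan batch as a block), 0.258 for translation factors (0.05) and 0.152 for the proteasome (-0.06, 22 of 29 lower; 0.0476 unpaired with array weights). It was 0.426 for nucleotide synthesis (0.02), 0.345 for amino acid synthesis (0.03), 0.622 for endoplasmic reticulum folding and secretion (-0.03), 0.814 for oxidative stress (0.02, negative under normexp), 0.7 for cell wall integrity signalling (0.05; 1 gene, CEK1, lower at -0.40, passed adjusted over the list alone with a p of 0.04, and not over all genes, with 0.072), 0.757 for protein mannosylation (-0.03) and 0.7 for zinc and copper (0.00, negative under median centring and quantile normalization). The fatty acid desaturase genes FAD3 and FAD2 were lower in 5 of 5 pairs, at -0.57 and -0.43 (adjusted p = 0.0519 and 0.0788). The drug transport gene NAG4 lay at -0.62 and NAG3 at 0.37 (adjusted p = 0.0592 and 0.0979), in opposite directions in 5 of 5 pairs each.

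One hypothesis is that transporters are overrepresented among the fallen genes. It was formed from the names of those genes, and the words searched for in the annotation (transporter, permease) were chosen from them, so the test cannot count as independent evidence. By the array annotation, 6 of the 45 fallen genes are transporters or permeases (13.3%), against 187 of the 6101 tested (3.07%), with a two-sided Fisher's exact p of 0.0023. They are TNA1, HGT12, GAP2, HGT10, HGT17 and orf19.3232. Of the 27 risen genes 2 are so described (7.41%; exact p = 0.2). The words searched for did not find TPO3, described above as an exporter, which also rose. These counts therefore depend on the wording of the annotation. Genes are not independent samples, so a reduced expression of uptake genes may be followed up only as a hypothesis.

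A second hypothesis was that the change with LL-37 lies along the main difference between the replicate numbers. The first component of the pair means held 70.2% of their variance. Across genes, which are not independent, the size of its correlation with the change was 0.36 (Spearman 0.366), between the limits of 0.3 and 0.5 set for and against, so the test leaves the question open.

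The value table's columns and the scanner files disagree on the replicate number in all 10 cases while agreeing on the group. The correlation of a column with the array of its own label was 0.947 to 0.992, against 1.0 with the array of another number. The paired and unpaired counts were computed with both sources.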
